A study of Staphylococcus lugdunensis with 5 samples.

How the data were processed

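Messenger RNA of Staphylococcus lugdunensis ATCC 43809, a skin commensal and opportunistic pathogen, was measured by RNA sequencing in 5 libraries. Per the labels' protocols, an overnight culture was diluted in tryptic soy broth (TSB) to an OD600 of 0.05 and grown at 37 °C and 250 rpm to an OD600 of 0.4, either with cell-free conditioned medium (CFCM) of Cutibacterium acnes ATCC 11827 or with a control medium, both at 2X. Cells were stabilised with a bacterial RNA protection reagent and lysed with lysozyme, lysostaphin and proteinase K, and the RNA was treated with DNase. Single reads of 100 bp were taken on a NextSeq 2000. The control group held 2 libraries and the CFCM group 3. The labels number the replicates without saying whether they were separate cultures, so the p-values here measure the spread between these samples only, which may be technical.

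The deposited table lists 2295 protein-coding genes with a product description and 1 value per library. The unit is not named in the table. Each column sums to 1000000 and the values are not whole multiples of 1 step. The deposited values were therefore treated as TPM, a unit scaled for gene length and library total, over the listed genes. FastQC, Trim Galore and DESeq2 are named in the submitters' processing notes, without versions. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here. TPM values keep no read totals, so the depth of each library is unknown and no interval or detection floor that needs read counts was computed. Of the low values of a library, between 14.0% and 30.1% lay within 0.1 of a whole multiple of its lowest value, so whole reads were not recovered. Genes carry identifiers of the form pgap_annot_ and a number and have no symbols, and their coordinates were not analysed here. Consecutive numbers are described as such and are not a measured genomic position. Reads shared between similar gene copies, if any, cannot be told apart from these values, and whether the 3 genes for beta-class phenol-soluble modulins are such copies was not examined.

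The design fixed before the data were examined foresaw a count model. Since the values are TPM, the test foreseen for tables without counts was used instead. Values were transformed as log2(TPM + 1), with a pseudocount of 1, and the groups were compared with limma 3.58.1 in R 4.3.3 (two-sided moderated test, variance trend on the mean level, no covariate) over all 2295 genes, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, CFCM minus control, and understate the change of genes with low values. Group values are TPM as mean ± SD, with n = 2 for control and n = 3 for CFCM throughout.

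Lists of genes were fixed before the data were examined, 28 in all, and members were found by a protein name or wording in the product description. The list of phage genes matched no row. The list of stable RNAs matched only proteins that act on RNA, since the table holds protein-coding genes, and was not tested. The other 26 lists had at least 3 members and were tested with camera at an inter-gene correlation of 0.01, two-sided, with adjustment over the 26 lists. Camera compares a list with all other genes. At the preset correlation its p-values, unlike those of single genes, rest on the spread across genes and not between the 5 libraries. The tests were repeated with an estimated correlation and with fry, which asks whether the members of a list move on balance one way. Its mixed test, which asks for change in either direction, was not in the fixed plan and does not compare a list with other genes. Product wording brought 14 rows into lists where they do not belong by function, such as 4 in the list of other amino acid biosynthesis, and their removal was tried as an alternative. Glutamine-hydrolyzing GMP synthase and several transglycosylases have wordings the fixed lists did not match.

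Genes are named by a rule fixed at the same time. It takes the 8 genes with the largest fold change in each direction among those past the threshold, with every CFCM library on the same side of both controls and a product other than hypothetical or of unknown function. It adds the members of each list with the smallest adjusted p among those past the threshold, up to 4 in the 4 lists the series title points to and up to 2 in the others. It also adds every member of the purine biosynthesis list, the pur operon repressor and the genes for the major autolysin, IcaA, LrgA and CidA where a row carries the name. No row carries the name of the major autolysin or of IcaA. Other genes named in the text were chosen after their values were seen.

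The steps were tested on simulated data for CFCM against control with the 2295 genes, 200 of them changed in each of 100 runs, and with a shared axis of deviation as strong as that in the real libraries. The test recovered 22.5% of the genes changed 1.5-fold, 58.0% of those changed 2-fold and 89.7% of those changed 4-fold, with a median of 0 false calls among 2095 unchanged genes. More than 100 false calls occurred in 5 runs, in each of which fold change and axis correlated across genes at an absolute r of at least 0.84. In the 28 runs in which the correlation across genes between fold change and axis was no stronger than the 0.18 of the real data, the highest number of false calls was 2. A list of 14 genes lowered 2-fold was found in 98 of 100 runs, and 3 of 2500 unchanged lists were called. The simulated genes, alone or in lists, were given independent noise apart from the axis. Library positions on the axis were drawn afresh in each run, so the closeness of CFCM 2 and CFCM 3 was not built in. The rates for single genes and for lists therefore do not cover genes that vary together, such as neighbouring genes.

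Alternatives were pseudocounts of 0.5 and 0.1, a filter at a mean TPM of 1, median-of-ratios scaling, a block for the replicate number, leaving out each library in turn, and, for lists, the estimated correlation, fry and membership by protein name only. Chosen after seeing the data were quantile normalization, a fit without the variance trend, averaging CFCM replicates 2 and 3, the first within-group axis as a covariate and the removal of misplaced rows from the lists.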

Results

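Transcript levels of 2295 protein-coding genes of Staphylococcus lugdunensis ATCC 43809 were compared between 2 libraries of cells grown with control medium and 3 libraries of cells grown with CFCM of Cutibacterium acnes, another skin bacterium. The series title names biofilm formation, autolysis and purine biosynthesis as its subjects, and the comparison addresses which transcripts differ when S. lugdunensis grows in medium conditioned by C. acnes. Median TPM per library lay between 62.5 and 74.4. The 4 genes with the highest mean levels, a cold-shock protein, a sterile alpha motif-like protein, an HU family DNA-binding protein and CspA, held 18.7% to 27.4% of the TPM of a library.

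Cells grown with CFCM had lower transcript levels of 10 of 14 purine biosynthesis genes. They had higher levels of the antiholin-like genes LrgA and LrgB and of 2 ABC transporter genes. Levels were also higher for 2 of 3 beta-class phenol-soluble modulins and 4 of 8 pyrimidine biosynthesis genes. As lists, purine and pyrimidine biosynthesis passed in camera at its preset correlation but not with an estimated correlation (adjusted p = 0.0949 and 0.391). Of the 2295 genes, 42 passed an adjusted p of 0.05 in limma, 24 higher and 18 lower with CFCM, and 36 of these differed at least 2-fold (22 higher and 14 lower). At an unadjusted p under 0.05 there were 310 genes. The count depended on every library. It was 7 without control 1, 4 without control 2, 27 without CFCM 1, 3 without CFCM 2 and 4 without CFCM 3. The 3 genes called in each of those 5 fits were LrgA, an ABC transporter ATP-binding protein and a YhgE/Pip domain-containing protein, whereas 16 of the 42 were called in none of them. All 42 kept their direction in each of the 5 fits, as they had to. In each called gene all CFCM libraries lay on the same side of both controls, so leaving out 1 library cannot turn the sign. Of the 10 called purine genes, 8 were called without CFCM 1 and 0 in each of the other 4 fits, while the median log2 fold change of the purine list stayed between -1.59 and -1.45.

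The libraries differed within the groups along 1 main axis. This axis held 88.8% of the within-group variance, with control 2 and CFCM 1 on one side and control 1, CFCM 2 and CFCM 3 on the other. With 5 libraries in 2 groups there are only 3 within-group directions, so a large share for the first is less remarkable. The 2 controls had to fall on opposite sides. CFCM 2 and CFCM 3 were closer to each other (Pearson r of log2 values across genes 0.998, median absolute log2 difference 0.083) than the 2 controls (r = 0.985 and 0.280). Without read counts, this could not be compared with sampling noise. With CFCM 2 and 3 averaged and counted as 1 library, 3 genes were called.

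Purine biosynthesis was the list with the lowest p. It holds the enzymes that build inosine monophosphate from phosphoribosyl pyrophosphate and convert it to the adenine and guanine nucleotides. Of its 14 members, 10 fell, none rose and 4 did not pass. These calls needed both controls, CFCM 2 and CFCM 3, since leaving out any of these libraries left 0 members called, and without CFCM 1 there were 8. The median log2 fold change of the 14 genes nevertheless stayed between -1.59 and -1.45 over the 5 fits. Adjusted over the list alone, all 14 passed. Because the series title names this pathway, the list may rest on these same samples and is not independent evidence of the direction. In all 14 genes every CFCM library was below both controls, which chance gives in 10% of genes and which held for 429 of all 2295 genes (18.7%). Since 11 of the 14 carry consecutive identifiers and may share a transcript, they do not count as independent. The median log2 fold change was -1.59, and camera gave an adjusted p of 3.76e-19 against all other genes. That value rests on the spread across genes and does not measure the spread between the libraries. With an estimated correlation the adjusted p = 0.0949, so that call was lost, and fry gave an adjusted p of 0.00113.

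Of these 14 genes, 11 carry consecutive identifiers, pgap_annot_001786 to pgap_annot_001796. The largest change among them was in phosphoribosylformylglycinamidine cyclo-ligase (pgap_annot_001793), which fell from 48.2 ± 3.95 TPM in control to 11.9 ± 1.57 TPM with CFCM (log2 fold change -1.93, SE 0.15, adjusted p = 0.00911). Phosphoribosylglycinamide formyltransferase (pgap_annot_001794) fell from 74.6 ± 2.83 to 18.8 ± 1.23 TPM (log2 fold change -1.93, SE 0.12, adjusted p = 0.00529). Amidophosphoribosyltransferase (pgap_annot_001792), which catalyses the committed step of the pathway, fell from 37.6 ± 2.09 to 9.49 ± 0.751 TPM (log2 fold change -1.88, SE 0.13, adjusted p = 0.00754). PurL (pgap_annot_001791) fell from 28.4 ± 2.94 to 7.60 ± 0.125 TPM (log2 fold change -1.77, SE 0.13, adjusted p = 0.00804). The bifunctional formyltransferase/IMP cyclohydrolase (-1.74), phosphoribosylformylglycinamidine synthase I (-1.69), phosphoribosylaminoimidazolesuccinocarboxamide synthase (-1.53), phosphoribosylamine--glycine ligase (-1.41) and 5-(carboxyamino)imidazole ribonucleotide mutase (-0.97) also fell, with adjusted p between 0.00911 and 0.0374. PurS (-1.66, SE 0.39, adjusted p = 0.157) and 5-(carboxyamino)imidazole ribonucleotide synthase (-1.04, SE 0.28, adjusted p = 0.195) had lower means but did not pass.

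**Figure D1:**
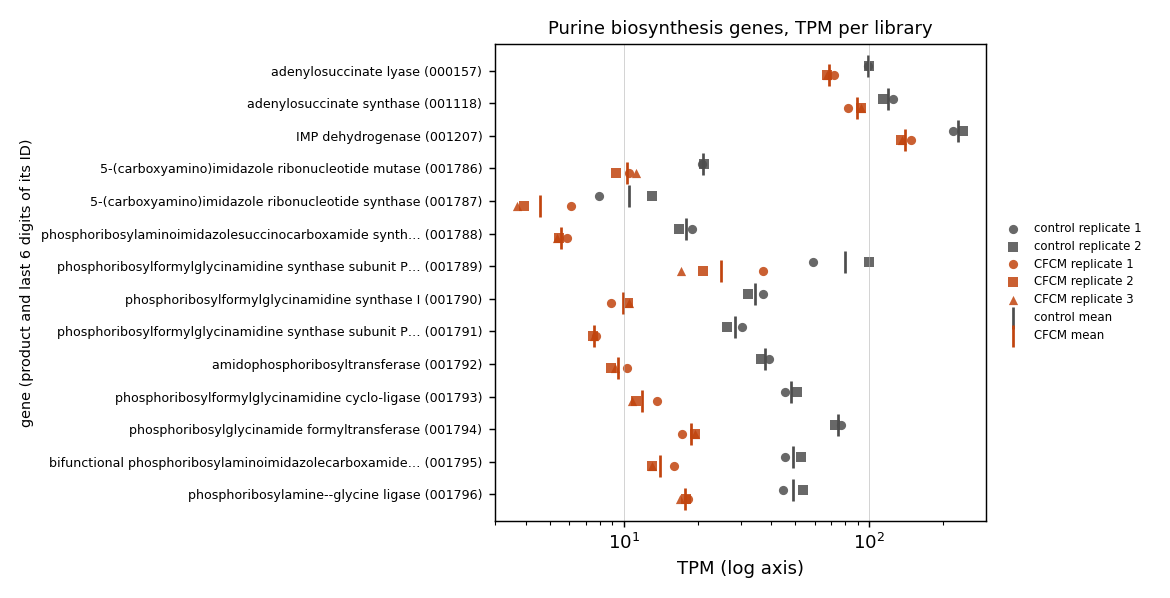
TPM (log axis) of the 14 purine biosynthesis genes in each of the 5 libraries, controls in grey and CFCM in red, with a bar at each group mean. In each of the 14 genes the 3 CFCM libraries lie below both controls, from 48.2 to 11.9 TPM on average in phosphoribosylformylglycinamidine cyclo-ligase.

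The 3 members outside this run had a median log2 fold change of -0.52, against -1.69 in the run, a difference that was not tested. IMP dehydrogenase (pgap_annot_001207), the first enzyme of the guanine branch, fell from 230 ± 16.5 to 139 ± 7.51 TPM (log2 fold change -0.72, SE 0.10, adjusted p = 0.0418). Adenylosuccinate lyase (-0.52, adjusted p = 0.0889) and adenylosuccinate synthase (-0.42, adjusted p = 0.187) did not pass. The pur operon repressor, PurR, which represses this pathway in other Gram-positive bacteria, was at 151 ± 4.64 TPM in control and 136 ± 4.96 TPM with CFCM (log2 fold change -0.15, SE 0.09, adjusted p = 0.556).

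The list of purine salvage and uptake had members in both directions and did not pass as a list (median log2 fold change -0.09, camera adjusted p = 0.702), but it passed fry's mixed test, which asks for change in either direction (adjusted p = 0.000138), as did 14 of the 26 lists in all. Of its 10 members, 1 rose, 1 fell and 8 did not pass, and adjusted over the list alone 2 rose and 2 fell. Product wording had brought in 3 of the 10 that do not belong by function. Without them camera gave an adjusted p of 0.239. A nucleobase:cation symporter-2 family protein (pgap_annot_001206) fell from 158 ± 19.0 to 64.4 ± 3.33 TPM (log2 fold change -1.28, SE 0.12, adjusted p = 0.0113). A NupC/NupG family nucleoside transporter (pgap_annot_000877) rose from 55.4 ± 4.34 to 167 ± 16.8 TPM (log2 fold change 1.57, SE 0.13, adjusted p = 0.00911). The neighbours by number of the symporter and of IMP dehydrogenase were looked up after the values were seen and did not pass. These were xanthine phosphoribosyltransferase (log2 fold change -1.23, adjusted p = 0.0501) and GMP synthase (-0.79, adjusted p = 0.0889).

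Pyrimidine biosynthesis changed in the opposite direction to purine biosynthesis. Of its 8 members, 4 rose and 4 did not pass, and adjusted over the list alone 6 rose (median log2 fold change 1.00, camera adjusted p = 8.03e-09, adjusted p = 0.391 with an estimated correlation, fry adjusted p = 0.0326). The small subunit of carbamoyl phosphate synthase, which makes the carbamoyl phosphate used for pyrimidines and arginine, rose from 57.5 ± 4.95 to 140 ± 10.3 TPM (log2 fold change 1.27, SE 0.12, adjusted p = 0.0113). Its large subunit rose from 64.8 ± 0.865 to 138 ± 3.86 TPM (log2 fold change 1.08, SE 0.09, adjusted p = 0.00911).

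The list of autolysis control joins LrgA and LrgB with related family proteins and regulators of autolysis. The antiholin-like LrgA and LrgB are known to restrain murein hydrolase activity and lysis in staphylococci. The product names of the related family proteins do not tell whether these share that role. Of the list's 12 members 4 rose, none fell and 8 did not pass, with the same count adjusted over the list alone. LrgA (pgap_annot_000602) had the largest fold change of all called genes, from 0.738 ± 0.265 to 23.1 ± 2.48 TPM (log2 fold change 3.80, SE 0.16, adjusted p = 0.00158). LrgB (pgap_annot_000603) rose from 3.97 ± 1.35 to 31.1 ± 11.3 TPM (log2 fold change 2.66, SE 0.33, adjusted p = 0.0291). A further pair rose less, a CidA/LrgA family protein (pgap_annot_000709) from 21.3 ± 2.75 to 56.6 ± 7.89 TPM (log2 fold change 1.37, SE 0.17) and an LrgB family protein (pgap_annot_000708) from 27.2 ± 2.08 to 61.5 ± 6.89 TPM (log2 fold change 1.15, SE 0.14), each with an adjusted p of 0.0291. The 8 members that did not pass, among them LytR, WalK, YycF and SarA, had log2 fold changes between -0.18 and 0.14. The list passed fry's mixed test (adjusted p = 0.00122), as did 14 of the 26 lists in all. The list rose on balance (camera adjusted p = 0.0459), but its median was 0.01, the call was lost with an estimated correlation (adjusted p = 0.562) and with fry (adjusted p = 0.0784), and without control 2 the adjusted p was 0.199.

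The genes in the list of autolysins and murein hydrolases did not differ between the groups beyond the spread of the libraries. The list stands for enzymes that cut peptidoglycan, but some members are named only for a peptidoglycan-binding LysM domain. No row carries the name of the major autolysin, so the list does not cover all such enzymes. None of the 13 members passed, over all genes or adjusted over the list alone, and the camera adjusted p was 0.396 (median log2 fold change -0.18, range -1.05 to 0.18, adjusted p = 0.842 with an estimated correlation and 0.749 in fry's mixed test). These genes varied strongly within the groups. Their median level was 55.3 TPM in control 1 and 104.9 in control 2, and 86.5, 71.2 and 65.2 in CFCM 1, 2 and 3. Of the 13 genes, 12 were higher on the side of the axis held by control 2 and CFCM 1, compared with 70.0% of all genes. Without control 1, the list was lower with CFCM at an adjusted p of 0.0142. The standard errors of these fold changes reached 0.59 on the log2 scale.

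**Figure D2:**
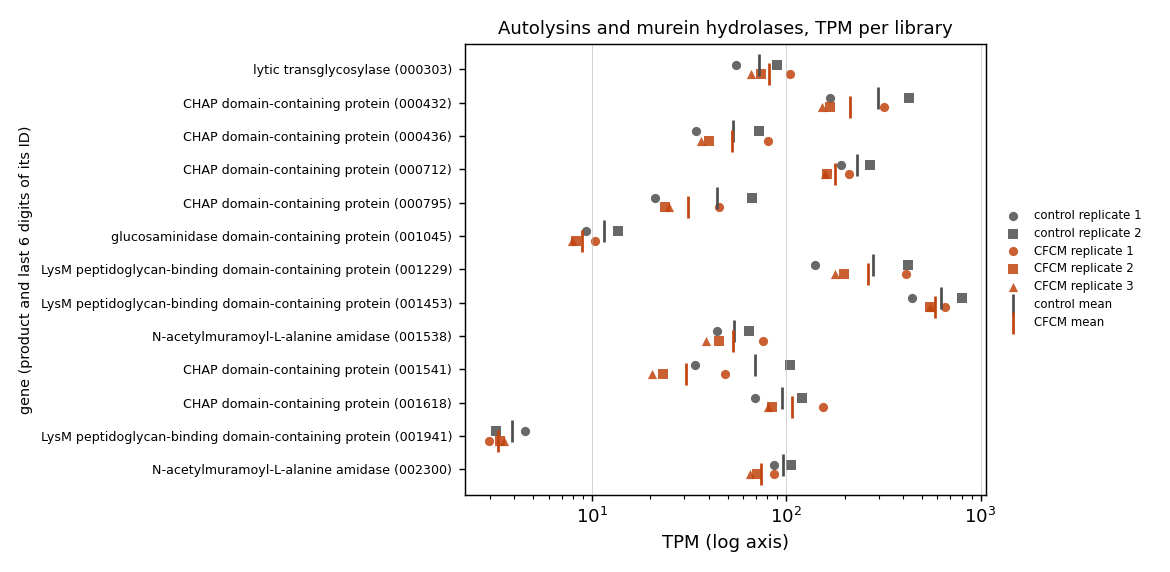
TPM (log axis) of the 13 autolysins and murein hydrolases in each of the 5 libraries, controls in grey and CFCM in red, with a bar at each group mean. The 2 controls lie far apart in many genes, with a median over the genes of 55.3 TPM in control 1 and 104.9 in control 2, and the groups overlap in all but 1 of them.

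Genes of the biofilm matrix and surface adhesins did not pass either. None of 11 members was called, over all genes or adjusted over the list alone (camera adjusted p = 0.702, adjusted p = 0.886 with an estimated correlation and 0.687 in fry's mixed test), and the test pointed up while the median was just below 0. IcaD, IcaC and the intercellular adhesin N-deacetylase, which make and export the polysaccharide of the biofilm matrix, had group means between 0.0755 and 0.352 TPM. At such levels the pseudocount of 1 flattens fold changes, so the test could hardly call these genes. IcaD had means of 0.0755 TPM in control and 0.257 TPM with CFCM, but a log2 fold change of 0.22. The highest log2 fold change was in a YSIRK-type signal peptide-containing protein (pgap_annot_000809, named after its value was seen), from 31.4 ± 20.7 to 97.7 ± 29.9 TPM (1.73, SE 0.47, adjusted p = 0.194).

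Of the 3 genes for beta-class phenol-soluble modulins, small amphipathic secreted peptides, 2 rose, as did the 2 ABC transporter genes numbered just before them. An ABC transporter ATP-binding protein (pgap_annot_000717) rose from 19.3 ± 2.01 to 171 ± 7.35 TPM (log2 fold change 3.09, SE 0.11, adjusted p = 0.00158). An ABC transporter permease (pgap_annot_000718) rose from 10.9 ± 3.90 to 111 ± 32.4 TPM (log2 fold change 3.24, SE 0.31, adjusted p = 0.0113). Whether both belong to 1 transporter was not examined. One modulin gene (pgap_annot_000720) rose from 269 ± 94.0 to 1843 ± 660 TPM (log2 fold change 2.76, SE 0.35, adjusted p = 0.0297) and another (pgap_annot_000721) from 35.2 ± 8.96 to 167 ± 33.9 TPM (log2 fold change 2.21, SE 0.23, adjusted p = 0.0152). The remaining modulin gene (pgap_annot_000719) had a log2 fold change of 1.94 and did not pass (adjusted p = 0.0702). Apart from the ATP-binding protein (0.06), the genes of this run had loads on the within-group axis above the median of all genes, with 0.74 for the permease and 0.77, 0.83 and 0.54 for the modulin genes pgap_annot_000719, pgap_annot_000720 and pgap_annot_000721 against 0.18. These modulins are the 2 called members of the 9 in the list of quorum sensing and global regulators, of which 3 rose adjusted over the list alone (median log2 fold change 0.12, camera adjusted p = 0.0459, adjusted p = 0.394 with an estimated correlation and 0.0784 with fry). That list's adjusted p was 0.199 without control 2 and 0.0759 without CFCM 3. Its regulators AgrB (0.09, SE 0.36) and SarA (0.14, SE 0.32) did not pass.

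**Figure D3:**
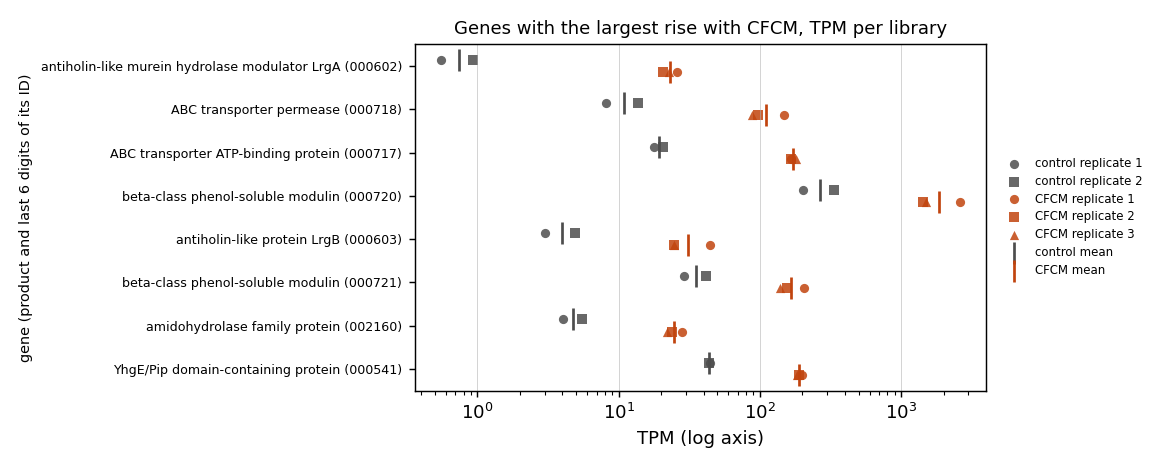
TPM (log axis) of the 8 named genes with the largest rise in each of the 5 libraries, controls in grey and CFCM in red, with a bar at each group mean. The 3 CFCM libraries lie above both controls in each gene, from 0.738 to 23.1 TPM on average in LrgA.

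The other 2 of the 8 named genes with the largest rise, like the transporter genes, belong to no list. A YhgE/Pip domain-containing protein (pgap_annot_000541) rose from 43.9 ± 0.544 to 190 ± 6.91 TPM (log2 fold change 2.09, SE 0.09, adjusted p = 0.00158). An amidohydrolase family protein (pgap_annot_002160) rose from 4.79 ± 1.07 to 24.7 ± 3.17 TPM (log2 fold change 2.16, SE 0.18, adjusted p = 0.00911).

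Among the remaining lists, arginine and urea metabolism rose (11 members, median log2 fold change 0.70, camera adjusted p = 6.86e-07, adjusted p = 0.391 with an estimated correlation and 0.0784 with fry). It passed fry's mixed test (adjusted p = 0.00130). Its called member was argininosuccinate synthase (pgap_annot_001698), which joins citrulline and aspartate on the way to arginine and rose from 115 ± 18.4 to 358 ± 14.8 TPM (log2 fold change 1.63, SE 0.13, adjusted p = 0.00911). The other 10 did not pass over all genes, and adjusted over the list alone 6 rose. Other amino acid biosynthesis was higher as a list (27 members, median 0.18, camera adjusted p = 0.0274, adjusted p = 0.842 with an estimated correlation and 0.687 with fry). Its adjusted p was 0.221 without control 1 and 0.0543 without CFCM 1. Aspartate kinase was its called member, from 2.32 ± 0.0269 to 5.38 ± 0.649 TPM (log2 fold change 0.94, SE 0.14, adjusted p = 0.0452), and 1 member passed adjusted over the list alone.

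Glycolysis was lower as a list although none of its 13 members passed singly over all genes, and adjusted over the list alone 5 fell (median log2 fold change -0.29, camera adjusted p = 0.0102, adjusted p = 0.656 with an estimated correlation, 0.182 with fry, 0.0769 without control 1). Glycolysis and iron uptake passed fry's mixed test (adjusted p = 0.0474 and 0.00130). Iron uptake was lower with no called gene among 8 members, 2 of which fell adjusted over the list alone (median -0.31, camera adjusted p = 0.0459, adjusted p = 0.394 with an estimated correlation and 0.0799 with fry). Its adjusted p was 0.199 without control 2 and 0.115 without CFCM 1. The list of the TCA cycle did not pass in camera (14 members, adjusted p = 0.309) but did in fry's mixed test (adjusted p = 0.00122), and its member AcnA, the aconitate hydratase, fell from 213 ± 3.54 to 87.0 ± 6.88 TPM (log2 fold change -1.28, SE 0.11, adjusted p = 0.00911), the 1 member that passed, also adjusted over the list alone.

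The other 14 lists held no gene past the threshold over all genes and did not pass as lists with all 5 libraries. Camera adjusted p values were 0.0553 for heat shock and proteolysis, 0.0689 for fatty acid synthesis, 0.0732 for the lugdunin locus and 0.178 for ribosomal proteins. They were 0.396 for fermentation and anaerobic respiration, 0.396 for peptide and amino acid transport, 0.417 for oxidative stress defence and 0.492 for carbohydrate uptake and use. Cell wall synthesis and modification was at 0.533, type VII secretion at 0.552, metal homeostasis other than iron at 0.552 and SOS and DNA repair at 0.702. Osmolyte uptake and synthesis was at 0.702, and branched-chain amino acid biosynthesis at 0.998. Of these 14, heat shock and proteolysis passed with fry (median log2 fold change 0.28, adjusted p = 0.00165), but not with an estimated correlation (adjusted p = 0.394). In fry's mixed test it did not pass (adjusted p = 0.239), whereas 6 others did. These were fermentation and anaerobic respiration (0.000225), branched-chain amino acid biosynthesis (0.00260), osmolytes (0.00482), carbohydrate use (0.0124), metal homeostasis (0.0129) and SOS repair (0.0162). Leaving out 1 library brought 4 of them past the threshold. Heat shock and proteolysis was higher at an adjusted p of 0.0258 without control 1 and 0.0192 without CFCM 1. Fatty acid synthesis (0.0212) and ribosomal proteins (0.0360) were lower without control 1, and the lugdunin locus (0.0122) was lower without control 2. Adjusted over the list alone, with all libraries, fermentation and anaerobic respiration had 7 called members, 2 higher and 5 lower, branched-chain amino acid biosynthesis had 1 higher, and the other 12 lists had none.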

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

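Quantile normalization, the fit without the variance trend, the average of CFCM 2 and 3, the axis covariate and the removal of misplaced rows were chosen after seeing the data. The count models, voom, count filters, library totals and removal of stable RNAs planned beforehand were not run, since the table holds TPM of protein-coding genes. Under other pseudocounts, the TPM filter, both scalings and the fit without trend, 41 to 61 genes were called, within 1.5 times the 42, and at least 37 of the 42 stayed called. Leaving out 1 library gave 3 to 27 genes (3 to 15 higher, 0 to 12 lower, 3 to 26 past 2-fold) and 3 to 22 of the 27 called named genes, and averaging CFCM 2 and 3 gave 3 genes (3 higher, 0 lower, 3 past 2-fold, 3 named). These fits have fewer libraries, and where a group is left with 1 library, limma takes its spread from the other group. At an unadjusted p under 0.05 they held 161 to 334 genes. The axis covariate gave 736 genes (355 higher, 381 lower), but on simulated data it made a median of 699 false calls over 100 runs, and 16.5 (highest 99) in the 28 runs with a correlation of fold change and axis no stronger than the real 0.18.

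Same-numbered libraries did not deviate together (correlations of -0.82 and -0.66). The deviations of the 2 controls are mirror images, so these values largely restate the main axis. They cannot exclude a smaller effect of pairing. With the replicate number as a block, 8 genes were called (8 higher, 0 lower, 8 past 2-fold, 7 named). The CFCM library without a same-numbered control is then fitted fully by its own block. The group difference in this fit rests on the 2 same-numbered pairs, and little is left to measure the spread. In camera with this block, iron uptake and other amino acid biosynthesis lost their calls (adjusted p = 0.0772 each). Calls lost with the block therefore cannot tell an effect of pairing from the loss of a library.

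The purine list was called in the other 16 fits run for it (adjusted p from 4.99e-27 to 0.00113) but not with an estimated correlation (0.0949). Too few of its members match by protein name for a test. Autolysis control was not called with an estimated correlation (0.562), fry (0.0784), protein names only (0.108) or the axis covariate (0.209), and ranged from 0.0195 to 0.199 without 1 library. The murein hydrolases ranged from 0.0142 (lower, without control 1) to 0.688 (higher, without control 2). Of 6 other lists called, 0 stayed with an estimated correlation. With protein names only, 3 of the 6 could be tested and 0 of all other lists tested were called. Of the 6, fry kept 1 (pyrimidine) and the axis covariate 3, and fry added heat shock. None of the 32 named genes changed sign in any fit, and 148 of 448 gene fits lost a call. Of the 32 genes, 27 were called in the main fit and so had a call to lose. In each of these genes all CFCM libraries lay on the same side of both controls. For this reason, or because the fold change itself stays the same, most fits could not turn a sign. Only median-of-ratios scaling and quantile normalization could have done so. The kept signs therefore say little beyond these scalings.

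The remaining changes of direction were in lists that were not called, or were not called under the alternative. They were the adhesins after quantile normalization (0.780), and with protein names only purine salvage (0.393), quorum sensing (0.911) and osmolytes (0.859). Branched-chain amino acid biosynthesis turned with the TPM filter (0.481), the block (0.957), the average of CFCM 2 and 3 (0.991) and without control 2, CFCM 1 or CFCM 3 (0.890 to 0.978 over the 5 fits without 1 library). Over the same 5 fits, fermentation (0.119 to 0.873) and carbohydrate use (0.192 to 0.873) turned only without control 1, each at the upper end, and SOS repair (0.619 to 0.990) only without CFCM 1, at the upper end. The cause of these changes was not tested. Read depth is unknown, so its limit on genes of low TPM was not assessed.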

Other observations

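The draws of random genes and the tests of explanations in this part were chosen after the results were seen, whereas the fold changes with their adjusted p, median-of-ratios scaling and the leaving out of single libraries were planned. The genes of this paragraph are called genes that the naming rule did not take, picked after their values were seen and not tested as a group. Type I glutamate--ammonia ligase (glutamine synthetase) fell from 896 ± 174 to 393 ± 36.1 TPM (log2 fold change -1.18, adjusted p = 0.0353), and the MerR family regulator numbered just before it fell from 2006 ± 331 to 927 ± 42.3 TPM (-1.10, adjusted p = 0.0291). Glutamine--fructose-6-phosphate transaminase, which uses glutamine for amino sugars, fell from 244 ± 17.3 to 120 ± 4.81 TPM (-1.01, adjusted p = 0.0113). An NCS2 family permease fell from 95.1 ± 3.84 to 55.2 ± 0.769 TPM (-0.77, adjusted p = 0.0297). A winged helix-turn-helix regulator and a pseudouridine-5'-phosphate glycosidase, numbered just before the NupC/NupG transporter, rose with it, from 38.2 ± 0.950 to 144 ± 3.70 TPM (1.89, adjusted p = 0.00218) and from 47.3 ± 3.49 to 158 ± 24.1 TPM (1.71, adjusted p = 0.0106). VraX, which binds C1q of complement, rose from 2208 ± 459 to 5698 ± 545 TPM (1.38, adjusted p = 0.0325).

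The 42 called genes formed 16 pairs with consecutive numbers, and 25 of the 42 had a called neighbour. Among 10000 random draws of 42 genes the highest number of pairs was 5 (one-sided permutation p = 0.0001, the smallest these draws can give). Neighbouring genes that share a transcript also share their chance deviations, so this does not exclude chance for any 1 run.

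The axis that separates control 2 and CFCM 1 from the other libraries appeared in both groups. The difference between the 2 controls and the difference of CFCM 1 from the mean of CFCM 2 and 3 correlated at r = 0.82 across genes, which are not independent replicates. Library scaling as the whole cause is argued against, since 82.8% of the axis's sum of squares remained after median-of-ratios scaling. Noise of weakly expressed genes is argued against by a correlation of 0.86 among the 1350 genes with a mean of at least 50 TPM. Exchanged labels of control 2 and CFCM 1 were looked at in the purine biosynthesis list. In it 14 of 14 genes had all CFCM libraries below both controls, though these genes are not independent of each other. The series title names this pathway, so the list may rest on these same samples under these same labels. It therefore cannot decide whether the labels were exchanged. A shared day of culture, growth state, RNA handling or a gene length effect stay open and were not tested, since neither dates nor gene lengths were used here, and no biological explanation was tested.

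The fall of the purine biosynthesis genes did not follow that axis. Their median log2 fold change was -1.61 after quantile normalization and -1.57 after median-of-ratios scaling, against -1.59 as reported, which argues against library scaling. The fold change predicted from the axis was 0.0089, which argues against leakage of the axis into the group difference. Purines supplied by the conditioned medium and a changed activity of the pur operon repressor may each give this pattern, and both stay open because neither the media nor repressor activity was measured.

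LrgA, LrgB, 2 phenol-soluble modulin genes and 2 transporter genes rose, and the remaining modulin gene (log2 fold change 1.94, adjusted p = 0.0702) did not pass. The median log2 fold change of these 7 genes was 2.76, and between 2.40 (without control 1) and 3.12 (without control 2) when 1 library was left out. Since 6 of the 7 were picked for a large rise in every CFCM library, this range does not test whether 1 library carries the pattern. Loads on the within-group axis were above the 0.18 median of all genes in 6 of the 7, among them LrgB (0.76) and LrgA (0.27). LrgB was at 44.2 TPM in CFCM 1 and 24.5 in each of CFCM 2 and CFCM 3, so the size of the rise differs by library. The agr quorum-sensing locus is a known activator of modulin genes in Staphylococcus aureus. Its higher transcription is argued against by its autoinducer peptide gene (log2 fold change -0.058, SE 0.12), for that gene only. AgrB of the same locus (0.09, SE 0.36) varied too much to tell. Transcripts of the locus that code for no protein are not among the listed genes. Activity of AgrA or of LytR without a change in transcript level may still contribute and was not measured.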
